A study of Mus musculus with 6 samples.

How the data were processed

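The data are RNA-seq of whole small intestine from 3 WT and 3 DTR libraries, grouped by the genotype that the labels give. The sample titled WT2 carries the description WT1, which is also that of the sample titled WT1; columns were matched by title, so which of WT replicates 1 and 2 is which rests on the titles, while their group does not. The labels do not say which mice shared a litter or day, nor outright that each library is a separate mouse, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, tissue was lysed in Trizol, RNA was purified with an RNeasy kit, and libraries followed standard Illumina procedures.

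The deposited values are log2 RPKM, reads scaled by gene length and library size, for 55487 genes in 6 libraries. Per the submitters' processing notes, the authors used FastQC, MultiQC, STAR, featureCounts, Subread and edgeR, with genome build mm10. Versions, strand setting and annotation release are not given in the sources used here, so overlapping and antisense genes cannot be separated. The deposited tables also give, per library, a total of reads in genes and a normalization factor, which is a ratio that rescales that total, and gene lengths and numbers of genes above given read depths. A table of percentages of genes above those depths was not used here. Undoing the log with a prior count of 0.25 scaled to library size gave whole reads for 100% of values within 1e-06, and their sums equalled the deposited totals of 61404574 to 76596766. These reads were used for read numbers and for an added fit only. Replicates within each group were compared by chi-square on their reads, which gave 95.4 to 544 per gene. No pair of replicates within a group looked like a repeat of the other. Pairs of a WT and a DTR library were not compared in this way.

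Gene symbols, classes and lengths come from the deposited values. Positions come from GENCODE M21, which uses the same build, where 55394 of 55487 gene IDs matched without their version. Positions are 1-based.

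The design and the tests below, the gene lists, the filter and most of the other settings were fixed before the data were examined. Genes with a mean log2 RPKM above -2 were tested, 15563 in all, of which 12597 are protein-coding and 1104 are long non-coding. The log2 RPKM of DTR and WT were compared with limma 3.58.1 in R 4.3.3, with a variance trend, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the scale of the deposited log values, which include a small prior count. For genes with few reads they depend on it, and a library with 0 reads can make the change larger than the ratio of mean RPKM. Of 40 fixed gene lists, 37 had at least 4 tested members and entered limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists; 13 passed, 9 lower and 4 higher. With an estimated correlation none of the 37 lists passed, and fry, which asks whether the members move one way on balance and does not compare them with other genes, passed 8. The 3 lists with fewer than 4 tested members are sex-linked genes, of which Xist was tested, mast cell and eosinophil genes (Mcpt1 -2.23, Prg2 -1.67, Mcpt2 -0.99) and gastric and Brunner gland genes (Tff2 -1.29, Pgc 0.25, Muc6 -0.38), none of the latter 6 passing. For neutrophil genes the median (0.11) and the mean (0.49) were positive while camera's direction was negative (adjusted p = 0.747). For germinal centre genes the median (-0.09) and the mean (-0.0064) were negative while camera's direction was positive (adjusted p = 0.811).

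Genes named in the text are Lgr5, then in each direction the 12 genes with the largest change among those past the threshold, with groups that do not overlap, a mean log2 RPKM above 0 and a symbol that is not a predicted model, then up to 4 members of each named list with the smallest p, and all members of lists with fewer than 5 tested; some genes that this rule picks are not reported here. Named after their values were seen were Olfm4, Ascl2, Axin2, Lyz1, Itln1, Mmp7, Pnliprp2, Clps, Muc2, Tff3, Mki67, Hbegf, Chaf1b, Slc11a2, Tfrc, Heph, Adipoq and the members of the lists drawn up for the closing section. Lgr5 falls below the expression filter and was fitted with all 43803 genes that varied.

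The test was tried on simulated values for 15563 genes with known changes in 50 genes per size. It recovered 10% of 1.5-fold, 46% of 2-fold, 88% of 4-fold and 96% of 8-fold changes, and called 3 of 15363 unchanged genes. The simulated spread was taken from the WT libraries for both groups, and far fewer genes were changed than passed in the data. The real DTR libraries varied more than the WT libraries, so these shares may not hold for the real comparison. Alternatives were pseudocounts of 0.1 and 1, no filter, a filter at 0, median centring, quantile normalization, a robust prior, no trend, array weights, a replicate block and leaving out each library. Chosen after the data were seen were limma's voom on the recovered reads, leaving out WT replicate 1 and DTR replicate 2 together, and autosomal genes alone. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.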

Results

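RNA from whole small intestine was sequenced in 3 wild-type libraries (WT) and 3 libraries from Lgr5-2A-DTR mice (DTR). In the DTR mice a diphtheria toxin receptor sits at the locus of Lgr5, a receptor gene that marks the stem cells at the crypt base, so that the toxin kills Lgr5-positive cells. Both genotypes were C57BL/6 adults older than 8 weeks, received 20 µg of diphtheria toxin per kg each day for 4 days, and were collected 6 h after the final injection. The comparison of DTR with WT asks what the loss of Lgr5-positive cells does to the tissue's transcripts. Reads assigned to genes numbered 71284256, 62092869 and 76596766 in WT replicates 1, 2 and 3, and 62538353, 64972540 and 61404574 in DTR replicates 1, 2 and 3.

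Lgr5 transcripts were close to absent in the DTR libraries. Lgr5 (ENSMUSG00000020140.15, mm10, chromosome 10, 115450311 to 115587780, minus strand) had 315, 254 and 229 reads in WT replicates 1, 2 and 3, and 22, 0 and 34 reads in DTR replicates 1, 2 and 3. Its mean level was 0.371 ± 0.0668 RPKM in WT and 0.0289 ± 0.0269 RPKM in DTR (SD, n = 3 each), a 12.9-fold difference of the means, and every DTR library lay below every WT library. The 0 reads in DTR replicate 2 allow a level of up to 0.00475 RPKM, the worth of 3 reads. The two-sided exact permutation test gave p = 0.1 (n = 3 each), the smallest value that 3 against 3 libraries can give. Lgr5 lay below the expression filter of the genome-wide test, so its log2 change of -5.40 (SE 2.20) comes from a limma fit of all 43803 genes that varied, in which it did not pass (adjusted p = 0.324). Across the other settings the adjusted p ranged from 0.0550 to 0.605, and the log2 change from -6.71 to -0.41. The log2 change rests on the prior count of the library with 0 reads: it was -3.11 without DTR replicate 2, -1.88 with a pseudocount of 0.1 and -0.41 with a pseudocount of 1. Mouse Hbegf, the counterpart of the primate gene that encodes the toxin receptor, stood at 3.75 ± 0.904 RPKM in WT and 30.3 ± 23.0 RPKM in DTR (SD, n = 3 each) and did not pass in limma (adjusted p = 0.0534).

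The groups also separated completely by sex-linked transcripts. Xist, the RNA that silences an X chromosome in female cells, had 28, 16 and 38 reads in WT replicates 1, 2 and 3 and 24279, 23259 and 22432 reads in DTR replicates 1, 2 and 3. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 9740, 12259, 6534 and 3999 reads over the WT libraries and 0 reads in every DTR library. Against a floor of 3 reads per library, Ddx3y was at least 962-fold higher in WT. Every comparison described here is therefore between libraries that differ in this sex pattern as well as in genotype.

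**Figure D1:**
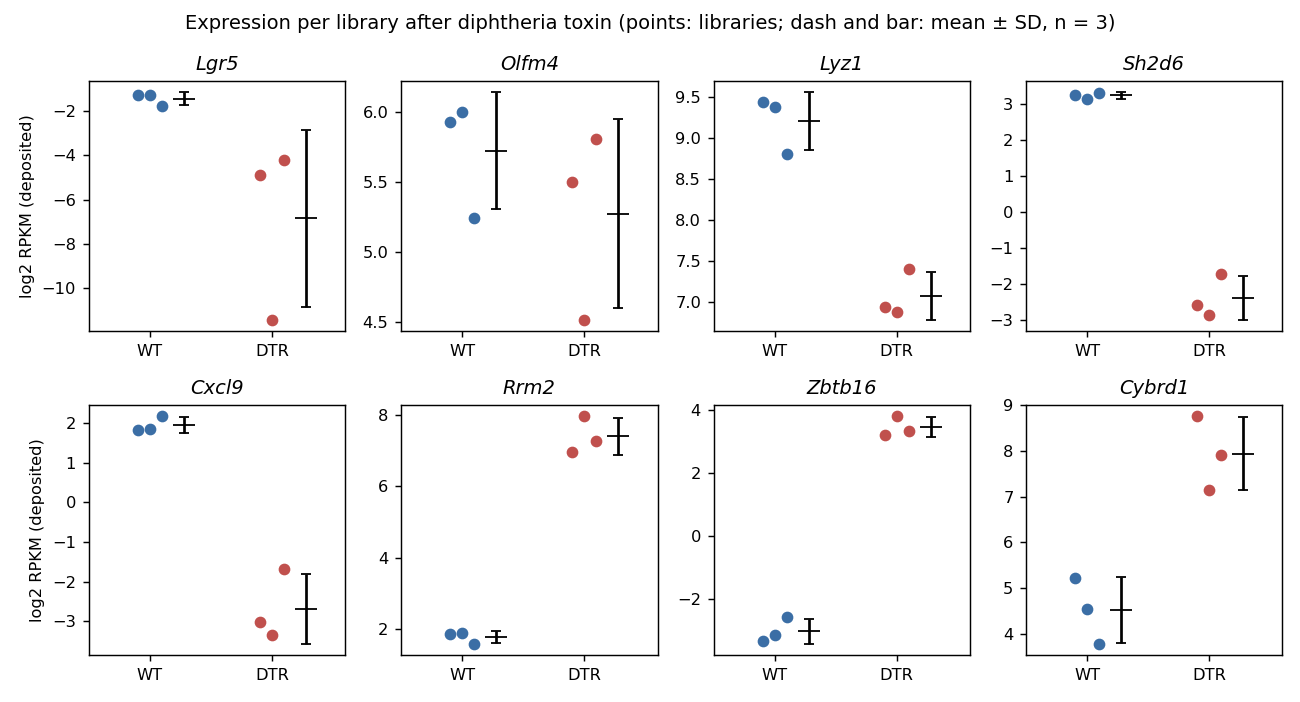
Deposited log2 RPKM (vertical axes) of 8 genes in WT and DTR libraries, with points for libraries and a dash and bar for the mean ± SD (n = 3 each). For 7 of the genes the groups do not overlap, whereas Olfm4 values of the groups do; the lowest Lgr5 point is the library with 0 reads, whose value is set by the authors' prior count.

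Among genes with a mean log2 RPKM above 0, groups that do not overlap and a symbol that is not a predicted model, the largest increases in DTR were in Zbtb16, Rasd1, the ribonucleotide reductase subunit gene Rrm2 and Fkbp5. Zbtb16, a zinc finger transcription factor (chromosome 9, 48654297 to 48836222), rose from a mean log2 RPKM of -3.03 ± 0.39 to 3.44 ± 0.32 (SD, n = 3 each; log2 change 6.47, SE 0.29; limma adjusted p = 0.00103). Rasd1, a dexamethasone-induced Ras protein, rose by a log2 change of 5.82 (SE 0.61), and Fkbp5, a co-chaperone of the glucocorticoid receptor, by 5.57 (SE 0.46). Rrm2, which makes deoxyribonucleotides (chromosome 12, 24708241 to 24714146), rose from 3.44 ± 0.375 to 177 ± 66.0 RPKM (SD, n = 3 each; limma adjusted p = 0.00103). The metallothionein Mt2 rose by 5.13 on the log2 scale, Gml by 4.48, Depp1 by 4.28, the haem oxygenase Hmox1 by 4.23, Gml2 by 4.14, the mTORC1 inhibitor Ddit4 by 4.11 and Lrg1 by 4.10. The Hmox1 call was lost in 10 of 18 other settings (limma adjusted p up to 0.215), and its DTR values ran from 8.07 to 211 RPKM.

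By the same limits, the largest decreases in DTR were in Cyp1a1, Mptx2, Apol10a and Cyp2c29. Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor (chromosome 9, 57687928 to 57703824), fell from 56.0 ± 60.0 to 0.0646 ± 0.0161 RPKM (SD, n = 3 each; log2 change -9.08, SE 0.85; limma adjusted p = 0.00531). Mptx2, a Paneth cell pentraxin (chromosome 1, 173274382 to 173277777), fell from 26.9 ± 2.56 to 0.161 ± 0.147 RPKM (SD, n = 3 each; limma adjusted p = 0.00522). Also falling were Apol10a (log2 change -6.25), the cytochrome P450 Cyp2c29 (-5.89), the tuft cell gene Sh2d6 (-5.63), the alpha-defensin genes Defa23 (-5.60) and Defa31 (-5.09), the eosinophil chemokine Ccl24 (-5.57), the glucuronosyltransferase Ugt2b38 (-5.43), Dnase1 (-5.23), the immunoglobulin segment Ighv1-69 (-5.17) and Apol7c (-5.00). The Ighv1-69 call was lost in 8 of 18 other settings (limma adjusted p up to 0.213). Reads of alpha-defensin genes and of immunoglobulin segments can be split among near-identical copies, so single members of these families are uncertain.

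In all, 2845 of 15563 tested genes changed at an adjusted p of 0.05 in limma, 1485 of them higher and 1360 lower in DTR, and 1808 changed by at least 2-fold (831 higher, 977 lower). Of the changed genes, 2740 lay on autosomes when those alone were tested. The WT and DTR values did not overlap for 47.7% of tested genes. Averaged over all splits of the libraries that share is 10% by construction. Genes move together, so a higher share for 1 split does not by itself exclude chance. The count depended on single libraries: it was 152 without WT replicate 1, 157 without WT replicate 2, 207 without WT replicate 3, 5605 without DTR replicate 1 and 1010 without DTR replicate 3. Of the 24 genes with the largest changes by the limits above, 12, 13 and 17 passed without WT replicates 1, 2 and 3, and 23 and 20 passed without DTR replicates 2 and 3.

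The libraries divided by genotype on the leading principal component, though not in every pairwise correlation. The DTR libraries differed more among themselves than the WT libraries. The leading principal component held 61.1% of the variance and placed all WT libraries on one side and all DTR libraries on the other. Across genes, Pearson's r between libraries was 0.970 to 0.973 within WT, 0.920 to 0.939 within DTR and 0.839 to 0.928 between groups. DTR replicate 1 correlated with WT replicates 1, 2 and 3 at 0.928, 0.928 and 0.921, and with DTR replicates 2 and 3 at 0.920 and 0.939. It was thus closer to each WT library than to DTR replicate 2. Genes are not independent replicates, and these values describe the libraries.

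**Figure D2:**
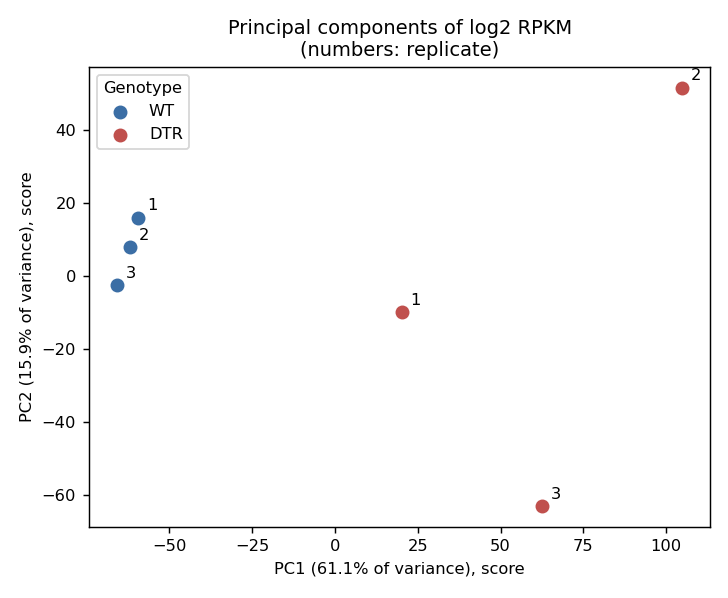
Scores of the 6 libraries on the leading 2 principal components of log2 RPKM (horizontal axis PC1, 61.1% of variance; vertical axis PC2, 15.9% of variance), with points for libraries and numbers for replicates. WT libraries lie close together and DTR libraries lie apart from them and from one another.

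Stem cell markers other than Lgr5 went both ways. Of 33 tested members of the stem cell list, 6 rose and 3 fell (7 and 4 adjusted over the list alone), the median log2 change was 0.29, and the list did not pass in camera (adjusted p = 0.374). The urea transporter Slc14a1 (log2 change -2.22) and Cd24a (-0.66) fell, while Arid5b (1.11) and the crypt transcription factor Sox9 (1.69) rose. Olfm4, a secreted marker of crypt base stem cells, differed by -0.45 (SE 0.37), the stem cell transcription factor Ascl2 by 0.50 (SE 0.59) and the Wnt feedback gene Axin2 by -0.69 (SE 0.49), and none of these passed. In the list of Wnt targets 4 of 17 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.325), with Myc (1.11), Sox9, Ephb3 (1.67) and Ephb2 (1.15) rising. Markers assigned to reserve stem cells (2 of 8 higher, 6 adjusted over the list alone; camera adjusted p = 0.0636) and to fetal-like regeneration (3 of 23 higher and 1 lower, 4 and 1 adjusted over the list alone; camera adjusted p = 0.145) did not pass. The reserve stem cell list passed in fry (adjusted p = 0.0412), with quantile normalization (0.0491) and without WT replicate 1 (0.0375), DTR replicate 2 (0.0199) or both (0.0124). The regeneration list passed with no filter (adjusted p = 0.0401) and without DTR replicate 1 (0.0390).

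A part of the cell cycle genes rose in DTR. All 30 mitosis genes had a higher mean in DTR and 9 passed (17 adjusted over the list alone), among them the spindle protein Nusap1 (log2 change 1.28), Anln (1.09), the survivin gene Birc5 (0.83) and the centromere histone Cenpa (1.04). The mitosis list had a median of 0.84 and passed in camera (adjusted p = 6.3e-06), but not with an estimated correlation (adjusted p = 0.721 with an estimated correlation). Of 28 DNA replication genes 5 rose (6 adjusted over the list alone), namely Rrm2, the sliding clamp gene Pcna (0.97), Dut (1.33), Hells (1.10) and Chaf1b, and the list passed in camera (median 0.71, adjusted p = 8.2e-05; adjusted p = 0.721 with an estimated correlation). In fry neither the mitosis (adjusted p = 0.114) nor the replication list (0.0760) passed. The proliferation marker Mki67 differed by 0.49 (SE 0.23) and did not pass.

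Among secretory lineages, Paneth and tuft cell genes fell steeply and goblet cell genes did not move as a group. In the Paneth list 20 of 28 members fell and none rose (21 lower adjusted over the list alone), with a median log2 change of -3.01 (camera adjusted p = 6.9e-12; adjusted p = 0.637 with an estimated correlation). Defa26 changed by -4.40, Defa17 by -2.80 and Defa24 by -2.58, the lysozyme gene Lyz1 by -2.13 (SE 0.23) and the lectin gene Itln1 by -2.29 (SE 0.21). The matrilysin, lipase and colipase genes Mmp7, Pnliprp2 and Clps, of which the latter pair is also abundant in pancreas, did not pass. In the tuft list 12 of 16 members fell (12 adjusted over the list alone), with a median of -2.75 (camera adjusted p = 7.7e-08; adjusted p = 0.129 with an estimated correlation). The regulator Rgs13 fell by 6.20 and Siglecf by 5.17 on the log2 scale. Of 22 goblet genes 1 rose (Galnt12, 0.77) and 1 fell (Clca1, -1.13), against 1 and 0 adjusted over the list alone. The goblet median was 0.020 and the camera adjusted p = 0.904. The mucin gene Muc2 differed by -0.12 (SE 0.12) and the trefoil gene Tff3 by -0.12 (SE 0.29), and neither passed. Of 22 enteroendocrine genes the hormone genes Cck (-1.44), Sct (-1.06) and Gcg (-1.42) fell (3 adjusted over the list alone), while the list did not pass (camera adjusted p = 0.0779). It passed with no filter (adjusted p = 0.0493), with a filter at 0 (0.0283), with array weights (0.0334) and without DTR replicate 2 (0.00381), alone or together with WT replicate 1 (0.0126).

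**Figure D3:**
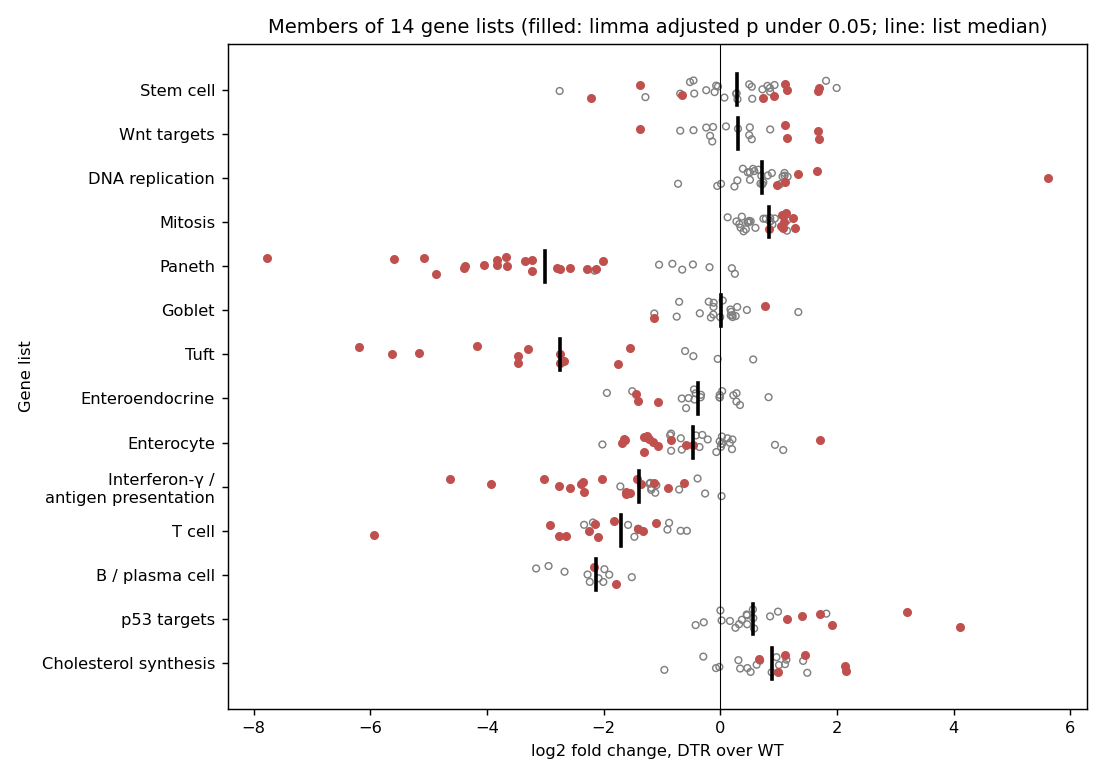
Log2 fold change of DTR over WT (horizontal axis) for tested members of 14 gene lists (vertical axis), with filled points for members past a limma adjusted p of 0.05 and a line at each list's median. Paneth and tuft medians lie at -3.01 and -2.75, and the goblet median at 0.020.

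Absorptive enterocyte genes were modestly lower. Of 35 members 12 fell and 1 rose (17 and 1 adjusted over the list alone), with a median log2 change of -0.46 (camera adjusted p = 0.00027; adjusted p = 0.637 with an estimated correlation). The peptidases Anpep (-1.66) and Enpep (-1.22) and the fructose transporter Slc2a5 (-1.07) fell, and the triglyceride synthesis gene Dgat2 rose (1.71). Markers of the villus tip (none of 10 changed, also adjusted over the list alone; camera adjusted p = 0.741) did not pass, nor did those of the distal small intestine (none of 5 changed, also adjusted over the list alone; adjusted p = 0.433). Among 10 genes of proximal small intestine, Cck and the lactase gene Lct (-1.16) fell and the duodenal ferric reductase gene Cybrd1 rose (3.43), counts that held adjusted over the list alone, and the list did not pass in camera (adjusted p = 0.199) but did in fry (adjusted p = 0.0412). Of 18 antimicrobial genes the lectin gene Reg3a (-2.34) and Il1b (-1.99) fell and the siderophore-binding gene Lcn2 rose (4.11), against 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.381).

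The lists of interferon-γ, T cell, B and plasma cell, macrophage and type I interferon genes passed as lower in DTR in camera, with between 2 and 17 members each falling, and those of neutrophil and germinal centre genes did not pass. In fry the T cell (adjusted p = 0.0564), B and plasma cell (0.114), macrophage (0.0564) and type I interferon (0.390) lists did not pass. Of 28 genes of the interferon-γ and antigen presentation list 17 fell (19 adjusted over the list alone), with a median log2 change of -1.39 (camera adjusted p = 2.5e-10; adjusted p = 0.637 with an estimated correlation). The chemokine Cxcl9 fell by 4.63 and the guanylate-binding proteins Gbp2, Gbp6 and Gbp7 by 2.33, 2.77 and 1.54 on the log2 scale. In the T cell list 11 of 20 fell (17 adjusted over the list alone; median -1.70; camera adjusted p = 4.6e-08; adjusted p = 0.637 with an estimated correlation), including Nkg7 (-2.16) and the receptor genes Cd3d (-1.82) and Trac (-2.64). In the B and plasma cell list 2 of 12 fell, Ighm (-2.17) and Derl3 (-1.79), against 8 adjusted over the list alone, with a median of -2.13 (camera adjusted p = 0.000361; adjusted p = 0.653 with an estimated correlation). The Ighm call was lost in 8 of 18 other settings (limma adjusted p up to 0.172) and that of Derl3 in 10 of 18 (up to 0.213). Of 16 macrophage and dendritic cell genes 6 fell and 1 rose, also adjusted over the list alone (median -0.63; camera adjusted p = 0.0311; adjusted p = 0.637 with an estimated correlation), with Tyrobp (-1.23) and Lyz2 (-1.36) lower and the haemoglobin scavenger receptor Cd163 higher (3.01). This call was lost without WT replicate 2 (adjusted p = 0.0564) and without DTR replicate 1 (adjusted p = 0.0792). Of 28 type I interferon genes 6 fell (8 adjusted over the list alone; median -0.29; camera adjusted p = 0.0218; adjusted p = 0.813 with an estimated correlation), a call lost without WT replicate 3 (adjusted p = 0.200), DTR replicate 1 (0.0541) or DTR replicate 3 (0.198, with a median of 0.0027). Of 7 neutrophil genes Mmp9 (-1.98) and Il1b fell and S100a8 rose (3.24), against 3 lower and 2 higher adjusted over the list alone (mean 0.49; camera adjusted p = 0.747). The S100a8 call rests on 14 reads over the WT libraries and was lost in 12 of 17 other settings, with log2 changes down to 0.85. S100a9, with 0 reads in 1 library, differed by 4.57 and did not pass (limma adjusted p = 0.0587). Of 7 germinal centre genes Ccl9 rose (0.82), also adjusted over the list alone, and none fell (camera adjusted p = 0.811).

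Stress and lipid genes changed in several directions. Of 23 p53 targets 6 rose (10 adjusted over the list alone), among them the cell cycle inhibitor Cdkn1a (log2 change 1.71), Ddit4, Plk3 (1.91) and the BH3-only gene Pmaip1 (3.20). The list of p53 targets passed in camera (median 0.56, adjusted p = 0.00079; adjusted p = 0.637 with an estimated correlation). Of 23 cholesterol synthesis genes 6 rose (12 higher and 1 lower adjusted over the list alone), including Lss (2.16), Cyp51 (1.45) and the regulator Srebf2 (1.10). The cholesterol list passed in camera (median 0.88, adjusted p = 0.00101; adjusted p = 0.721 with an estimated correlation) but not in fry (adjusted p = 0.130). Fatty acid oxidation genes did not pass as a list (camera adjusted p = 0.19), although Angptl4 (3.35), Acot2 (1.74), Acot1 (2.55) and Acadl (0.81) were among 6 of 24 that rose and 2 fell (10 and 4 adjusted over the list alone). Of 15 clock genes 5 rose, among them Cry2 (2.53), Per1 (2.68) and Npas2 (1.16), and Dbp fell (-1.76), against 5 and 2 adjusted over the list alone (camera adjusted p = 0.188). Of 20 unfolded protein and integrated stress genes Herpud1 rose (1.44) and 5 fell, among them Creld2 (-0.88), Hsp90b1 (-0.68) and Ddit3 (-1.33), against 3 and 8 adjusted over the list alone (camera adjusted p = 0.0779). That list passed in fry (adjusted p = 0.0412), with no filter (0.0401) and with a filter at 0 (0.0370). Immediate early and heat shock genes did not pass as a list (camera adjusted p = 0.187), with 2 of 16 higher, Dusp1 (2.92) and Fos (1.81), and 1 lower, Hsph1 (-1.61), against 3 and 1 adjusted over the list alone. That list passed with array weights (adjusted p = 0.0481) and without DTR replicate 1 (0.00364).

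Markers of tissues next to the epithelium were examined beside these groups. The red cell list fell in camera (2 of 4 members lower, 3 adjusted over the list alone; median -2.73; adjusted p = 0.0159; adjusted p = 0.653 with an estimated correlation), a call lost without DTR replicate 1 (adjusted p = 0.0835) and in fry (adjusted p = 0.0760). Its members are Hbb-bt (-3.32) and Hbb-bs (-2.94), which fell, and Hba-a1 (-2.51) and Hba-a2 (-1.54), which did not pass. Pancreatic enzyme and insulin genes took 2.65, 7.01 and 2.46% of reads in WT replicates 1, 2 and 3 and 5.08, 1.44 and 2.06% in DTR replicates 1, 2 and 3. That list did not pass (camera adjusted p = 0.17), although it passed without WT replicate 1 (adjusted p = 0.0343) and without DTR replicate 1 (adjusted p = 0.0328). Fat cell genes had a mean log2 RPKM of 2.44 in WT replicate 1 and 4.35 in DTR replicate 2, against 0.56 and 0.46 in WT replicates 2 and 3 and 1.07 and 0.67 in DTR replicates 1 and 3 (camera adjusted p = 0.381). The lists of smooth muscle (adjusted p = 0.904), fibroblast (0.425), endothelial (0.693), enteric neuron and glia (0.408) and mitochondrially encoded genes (0.858) did not pass in camera. Single members did: 1 of 17 smooth muscle and 2 of 19 fibroblast genes fell and 1 of 14 endothelial genes rose, also adjusted over the list alone. None of 10 enteric neuron and glia genes and none of 13 mitochondrially encoded genes changed.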

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

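The fit of recovered reads, the fit without WT replicate 1 and DTR replicate 2 together, and that of autosomal genes were chosen after the result was seen. No test that passed changed direction, although the median of the type I interferon list turned from -0.29 to 0.0027 without DTR replicate 3, where the list did not pass. The 2845 changed genes became 828 with no filter, 4862 with array weights, 152 without WT replicate 1 and DTR replicate 2 together, and 152 to 5605 when 1 library was left out; other settings gave 2298 to 3367. The 1808 genes changed by at least 2-fold became 1016 with a pseudocount of 1, 631 with no filter, 152 without that pair, and 152 to 3272 when 1 library was left out. With the replicate number as a block the counts were 1161 and 1044. Same-numbered libraries deviated together by r = -0.0109, -0.00244 and 0.165, and other WT and DTR pairs by -0.123 to 0.114. These values do not settle whether the numbers pair the samples. The main fit has no block because the labels do not say that equal numbers share a litter or day. Each fit without 1 library has equally few samples, so sample number alone does not account for the spread of changed-gene counts. They were 152, 157 and 207 without WT replicates 1, 2 and 3, and 5605, 2405 and 1010 without DTR replicates 1, 2 and 3. The DTR libraries varied more than the WT libraries. Whether that difference in spread sets these counts was not tested. The 13 lists past the threshold became 0 with an estimated correlation and 8 with fry, 5 of them shared, and 12 to 15 when 1 library was left out. Lgr5 kept its direction, with log2 changes of -6.71 to -3.11 when 1 library was left out and -1.88 and -0.41 with pseudocounts of 0.1 and 1, and passed in no setting. Of 134 genes picked for naming that passed, 37, 37 and 44 passed without WT replicates 1, 2 and 3, 134, 113 and 90 without DTR replicates 1, 2 and 3, 132 with voom, 102 with the replicate block, 43 with no filter and 28 without WT replicate 1 and DTR replicate 2 together. Calls lost in 8 or 9 of 17 or 18 other settings include Ephb3, Cenpa, Clca1, Hsp90b1, Dusp1, Fos, Hsph1 and Chaf1b. Low read numbers limit the fit of Lgr5, which had 798 reads over the WT libraries and 56 over the DTR libraries. Its log2 change rests on the prior count of the DTR library with 0 reads.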

Other observations

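Enzymes that process foreign compounds were lower in DTR well beyond Cyp1a1 and Cyp2c29. In a list of such genes drawn up after the top genes were seen, leaving those out, 17 of 30 members fell and 1 rose. The median log2 change was -1.16 (camera p = 1.3e-08, and p = 0.0666 with an estimated correlation). The member that rose was Tiparp (0.89, limma adjusted p = 0.0493), and the other 12 did not pass, among them Cyp1b1 (1.24). The cytochrome P450 genes Cyp2c55 (log2 change -3.74, SE 0.73) and Cyp2b10 (-1.91, SE 0.24), the glucuronosyltransferases Ugt2b36 (-2.85) and Ugt1a6a (-2.35) and the quinone reductase Nqo1 (-1.26) fell in limma. The ferric reductase gene Cybrd1 (3.43) and the iron transporter gene Slc11a2 (3.77, SE 0.66; limma adjusted p = 0.0199) rose, while the iron genes Tfrc (0.54) and Heph (0.09) did not pass. Slc11a2, Tfrc and Heph were singled out after their values were seen, Tfrc and Heph from the hypoxia list below once its test had been run.

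Of the tests below, the split of the libraries, the glucocorticoid list and the hypoxia list were set before their results were seen, and those on the sex chromosomes, sex of the mice, fat tissue, dilution and alpha-defensin reads were chosen after. The number of changed genes was 2845 for the real grouping and at most 0 for the other splits of the 6 libraries. Only 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each other split mixes WT and DTR libraries within its groups. The difference between genotypes then adds to the spread within groups, so few calls were likely and the 0 says little. Genes on the sex chromosomes account for little of the count, since autosomes tested alone gave 96.3% as many called genes. Autosomes held 15106 of the 15563 tested genes, so a high share was bound to result. Whether the sex of the mice contributes on autosomes cannot be told apart from genotype, because 0 libraries belong to a genotype that occurs in both sexes by their Xist and Y-linked reads.

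The genes highest in DTR may reflect a glucocorticoid response, a hypothesis formed from Zbtb16, Fkbp5 and Rasd1. Among glucocorticoid-induced genes whose values had not been seen, 9 of 18 rose, including Hif3a (4.72), Sgk1 (2.96) and Map3k6 (2.79). Hif3a was low in WT (mean log2 RPKM -4.23), and its change was as small as 1.21 in other settings. Its call was lost in 1 of 17 other settings, that of Map3k6 in 5 of 17 and that of Sgk1 in 0 of 18. The median was 1.21 (camera p = 2.9e-06, and p = 0.137 with an estimated correlation). The other 9 did not pass, among them Tsc22d3 (0.78), Cebpb (0.66), Nfkbia (0.58) and Klf9 (0.54), though each had a positive change. A hypoxia response is another candidate explanation. Of 19 hypoxia-induced genes not seen before that test, 5 rose, including Ndrg1 (2.48), Adm (2.47), Bhlhe40 (2.02) and Car9 (1.44). The median was 0.50, only just above the bar of 0.5 set beforehand (camera p = 0.00415, and p = 0.0357 with an estimated correlation). The other 14 did not pass, among them Vegfa (0.35) and Pdk1 (0.12). Of these, Pfkfb3 (-1.13), Pfkfb4 (-0.65) and Mxi1 (-0.31) had negative changes. Fat tissue in the DTR samples is argued against as the whole cause: of 10 fat cell genes, 2, Fabp4 and Cidec, were higher in every DTR library than in every WT library, while the fat hormone gene Adipoq stood at 0.180 and 0.221 RPKM in DTR replicates 1 and 3 and at 3.02 RPKM in WT replicate 1. Both responses and the sex of the mice stay open, and the loss of Lgr5-positive cells was not tested apart from them.

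The fall of the Paneth, tuft and T cell lists could in principle be dilution by other tissue. Dilution of the whole epithelium would lower goblet genes alike, and their median was 0.020 (quartiles -0.19 and 0.21). This argues against such dilution for the Paneth and tuft lists. Goblet genes cannot show a smaller share of crypt base or of the tissue that holds T cells, so neither was tested. Splitting of reads among alpha-defensin copies does not account for the Paneth part: summed over 39 alpha-defensin genes, levels in CPM were 1527 ± 332 in WT and 196 ± 56.1 in DTR (SD, n = 3 each), 7.80-fold higher in WT. Genotype, through the ablation of Lgr5-positive cells, and the sex of the mice both remain open for this pattern.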
